A study of Xenopus laevis with 4 samples.

How the data were processed

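The series profiled ETS2 binding by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in whole embryos of the frog Xenopus laevis. Per the labels, embryos had received 750 pg of mRNA for ETS2 carrying a triple FLAG tag and were collected in mid-gastrulation, at stage 11.5. ETS2 is a transcription factor of the ETS family, and the FLAG tag is a short peptide that an antibody recognises. The 4 libraries fall into 2 groups by their labels. The first group holds 2 ChIP libraries made with the FLAG antibody, and the second holds 2 input libraries made without antibody. The ChIP libraries are called library 1 (letter A in the labels) and library 2 (letter C). The labels tie library 1 to the input lettered D and library 2 to the input lettered F, because each such pair lists the same peak file. Nothing in the labels says whether the libraries came from separate clutches or batches of embryos.

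Bowtie2 2.2.3 and MACS2 are named in the submitters' processing notes, without their role, their settings or the version of MACS2. The genome build is not given in the sources used here. The authors deposited 1 list of peaks per ChIP library, with the start and end of each peak and a value per peak that the files do not name. As deposited, this value was read as −log10 of a p-value or q-value, from its range and lower limit, and which of these it is remains open. The lowest deposited −log10 values were 1.33 in library 1 and 1.31 in library 2, just above 1.30, which is −log10 of 0.05. The value is called the peak value below. It is the authors' own and was used only to rank, describe or filter peaks. Because such a value grows with the number of reads, it is not comparable in size between libraries, and ranks within each list were used where the libraries were combined. The authors also deposited a list of common regions that holds coordinates and no value. Every common region contained at least 1 peak of each library. In all 61137 regions the bounds equalled the outermost bounds of the peaks inside, so the list was a merge of overlapping peaks from both lists.

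Read counts and sequencing depth are unknown, since the files are peak lists, and no count of reads was tested. The precision of a share of peaks is given as an exact (Clopper-Pearson) 95% binomial interval, which covers counting error only. Neighbouring peaks are not independent, and the replication is that of 2 ChIP libraries. The libraries were compared with each other by the overlap of their peaks, by the ranks of their peak values and by repeating the L to S comparison in each list.

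Peaks of the libraries were taken as shared where they overlapped by at least 1 bp. The overlap was compared with 100 random placements of the peaks of library 1 within their own chromosomes, made with bedtools shuffle 2.31.1 on the 18 chromosomes, as a one-sided permutation test. With 100 placements, 0.0099 is the smallest p this test can give. Lengths of chromosomes and scaffolds were taken as the end of the last peak on each in any list, so that scaffolds without a peak are left out, because no genome of the build of the files was used. The agreement of peak values was given as Spearman's rank correlation across overlapping peaks, without a p-value. The percentile rank of a common region in a library was that of its highest peak in that library's list, and its mean over both libraries ranked the regions. Regions named one by one are the 10 with the highest mean percentile rank. Densities on the L and S chromosomes were compared by an exact two-sided sign-flip permutation test over the 9 chromosome pairs. These tests, the rule for named regions and part of the alternatives were fixed before the data were examined. The grouping of regions along the chromosomes and the dense windows were examined afterwards. Start positions are printed counting from 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

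The overlap, sign-flip and pairing procedures were tested on simulated data. Of simulated lists of 61583 peaks on the chromosomes with 90% of peaks copied between libraries, an overlap of 90.2% was recovered. For 9 simulated chromosome pairs, a planted L to S ratio of 1.1 came back as 1.10 and passed the threshold of 0.05 in 100% of 50 simulated sets, and with equal densities 8% of 50 sets passed. Planted shared profiles of partner chromosomes passed in 10 of 10 simulated sets, and unrelated profiles in 0 of 10. These settings were easier than the data. The planted ratio of 1.1 was above the observed 1.077, and little spread was added to the simulated densities beside counting error. Planted profiles were identical in both partners, while the observed mean rank correlation of partners was 0.216. The pass rates therefore do not give the power for patterns as weak as those observed.

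Of the 7 results planned, 3 were not run. These were the location of peaks relative to genes, the search for binding motifs and the comparison of gene lists. They need a genome or gene models of the build of the files. The gene table used here to look up names belongs to the assembly Xenopus_laevis_v10.1. Its genes extend past the last peak on 18 of the 18 chromosomes, which cannot tell whether the assemblies differ, since genes can lie past the last peak within the same assembly. Because the build of the files is not given, the coordinates of this table were not used and no peak was assigned to a gene.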

Results

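Binding of FLAG-tagged ETS2 was mapped across the genome of Xenopus laevis embryos in mid-gastrulation (stage 11.5), after injection of 750 pg of its mRNA. ETS-family factors are known nuclear targets of the FGF and MAP kinase pathway, which patterns the mesoderm at this stage. The design asks which regions were called as peaks in both ChIP libraries and how these regions were spread over the L and S chromosomes of this allotetraploid frog. The data comprise 2 ChIP libraries and 2 inputs, as 1 peak list per ChIP library and 1 list of common regions. All libraries came from embryos that carried the tagged protein, and a ChIP from embryos without it was not analysed here. The depth of the libraries is unknown.

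Library 1 gave 69083 peaks and library 2 gave 157105, which is 2.27 times as many. Peaks of library 1 had a median width of 220 bp (interquartile range 141 to 330) and covered 18.2 Mb, or 0.683% of the sequence spanned by peaks. Peaks of library 2 had a median width of 280 bp (193 to 423) and covered 54.6 Mb, or 2.05%. The smallest width was 94 bp in library 1, held by 2445 peaks, and 139 bp in library 2, held by 6064 peaks. Each list thus had its own lower limit of width, which bears on these comparisons of width and cover. The median peak value (read as −log10 p or q, since the files do not name it) was 8.34 in library 1 and 10.5 in library 2, and the highest values were 150 and 299. With the same minimum value of 20 in both lists, 12986 peaks of library 1 and 50152 of library 2 were left, a ratio of 3.86, although values are not comparable in size between libraries of unknown depth. The counts have no error of their own, because there is 1 list per library.

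Nearly all peaks of library 1 overlapped a peak of library 2. Of the peaks of library 1, 66454 (96.2%, 95% interval 96.0 to 96.3%) overlapped a peak of library 2, and 2629 did not. Of the peaks of library 2, 61284 (39.0%, 38.8 to 39.3%) overlapped a peak of library 1, and 95821 did not. On the chromosomes alone the shares were 97.1% and 38.8%. Randomly placed peaks of library 1 met a peak of library 2 in 3.51% ± 0.0681 of cases (SD over 100 placements, highest 3.70%), so the observed overlap exceeded every placement (permutation p = 0.0099, one-sided, the smallest that 100 placements can give). As the placements were uniform up to the last peak, without regard to sequence gaps or gene density, this p speaks only against uniform placement. When library 2 was reduced to its 69083 highest peaks, 76.1% of them overlapped a peak of library 1, and 83.3% of library 1 peaks overlapped one of them. When each peak of a pair had to cover at least 50% of the other, 49.5% of library 1 and 21.8% of library 2 peaks remained shared.

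The overlap rule itself places shared peaks close together, so their distances are given as a description and were not tested. The midpoints of the 66601 overlapping pairs were a median of 40 bp apart (17 to 87), and 89.2% of library 1 peaks in these pairs lay wholly inside the library 2 peak, which was wider (median 469 against 227 bp). A common region held 2 or more peaks of library 1 in 4671 of 61137 cases (7.64%) and 2 or more peaks of library 2 in 147.

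The share of library 2 peaks found in library 1 rose with their value. It was 3.60% (3.31 to 3.90%) in the lowest decile, 16.2% (15.6 to 16.8%) in the fifth, 76.0% (75.3 to 76.7%) in the eighth and 99.9% (99.8 to 99.9%) in the highest. Peaks of library 1 were found in library 2 at 87.8% (87.0 to 88.6%) in their lowest decile and at 99.4% (99.2 to 99.6%) in their highest. Library 2 peaks with a partner had a median value of 35.5 and a median width of 450 bp, and those without one had 6.43 and 216 bp.

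**Figure D1:**
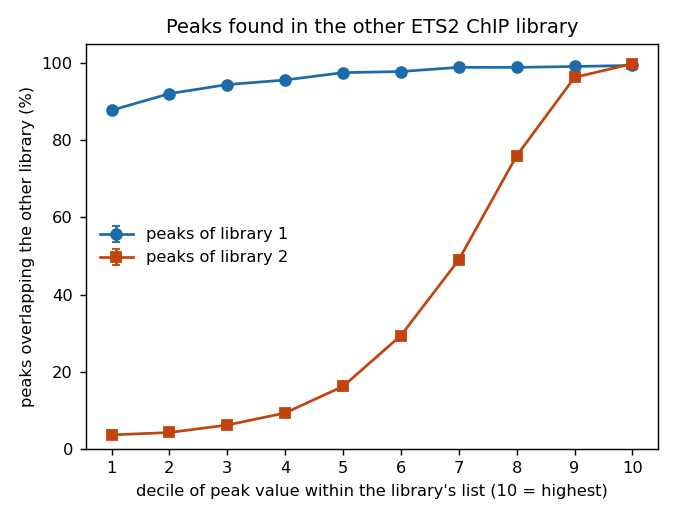
Share of peaks (%, y axis) that overlap a peak of the other ETS2 ChIP library by at least 1 bp, by decile of peak value within each library's list (x axis, 10 is the highest). Points are shares of all peaks in a decile and bars are exact 95% binomial intervals, mostly smaller than the points; library 2 rises from 3.60% to 99.9%, while library 1 starts at 87.8%.

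Strong sites of one library were strong in the other. Across the 66601 overlapping pairs, the rank correlation of peak values was 0.70, given without a p-value because peaks are not independent replicates. It was 0.79 across the 34213 pairs with reciprocal overlap and 0.51 after adjustment for the widths of both peaks, since wider peaks had higher values in both libraries (rank correlations of 0.70 in library 1 and 0.55 in library 2). Of the 6115 common regions with the highest rank in library 1 (the top 10%), 4318 (70.6%) were also in the top 10% of library 2, where independent ranks would give 10%.

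**Figure D2:**
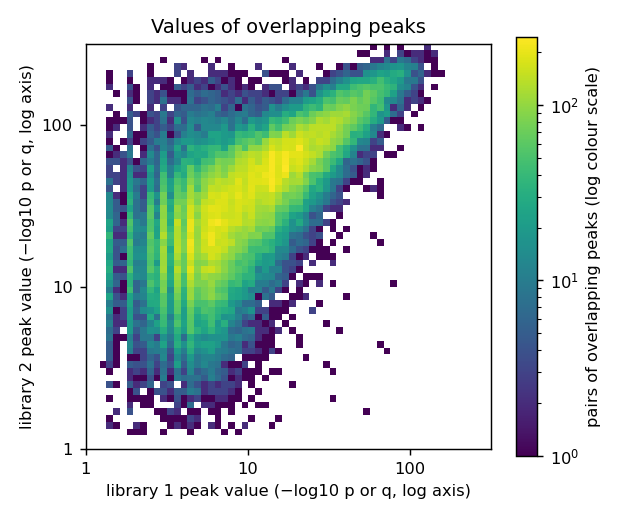
Peak values (−log10 p or q, logarithmic axes) of the 66601 pairs of overlapping peaks, library 1 on the x axis and library 2 on the y axis; colour gives the number of pairs per cell on a log scale. The rank correlation is 0.70; values are not comparable in size between the libraries.

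The 10 common regions with the highest mean percentile rank were 710 to 1622 bp wide, with peak values of 112 to 144 in library 1 and 226 to 298 in library 2. Each ranked above the 99.9th percentile of both lists. Coordinates are those of the files, whose genome build is not given in the sources used here, and no gene was assigned. The highest was on chromosome 8S at 93280459 to 93281390, with values of 139 in library 1 and 280 in library 2. The next was on 8L at 21219799 to 21220907, with values of 131 and 298. The region on 6L at 108370320 to 108371941 was the widest, at 1622 bp, and had values of 137 and 269. A region on the unplaced Scaffold1440, at 657 to 1542, had values of 131 and 275. The region on 5L at 23993430 to 23994807 had values of 125 and 295. Chromosome 3S carried a region at 26145799 to 26146782 (118 and 271) and another at 4968185 to 4969023 (144 and 238). Chromosome 3L carried a region at 117680951 to 117682072 (129 and 254) and another at 23196140 to 23196849 (112 and 262). The last of the 10 was on 2S at 86550262 to 86551067, with values of 141 and 226.

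Common ETS2 regions were found on all 18 chromosomes. They numbered 55441, or 22.1 per Mb. Chromosomes 9_10L (27.6 per Mb), 8L (27.4) and 8S (27.0) were densest, and 5S (18.7), 6S (19.2) and 1S (19.2) were sparsest. The median percentile rank of the regions ranged from 63.9 on 6L to 67.6 on 8L. A further 5696 common regions (9.32%) lay on 2102 unplaced scaffolds, led by Scaffold20 with 335 regions and Scaffold22 with 269, and their median percentile rank was 64.5 against 66.1 on the chromosomes.

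Among regions placed on chromosomes, the L chromosomes carried slightly more per Mb than their S partners. Xenopus laevis holds L and S subgenomes that derive from different ancestral species, and its chromosomes come as 9 pairs of an L and an S version. There were 31313 common regions on L chromosomes (22.9 per Mb) and 24128 on S chromosomes (21.2 per Mb). The geometric mean of the L to S ratio over the 9 pairs was 1.08 (mean log2 ratio 0.11 ± 0.083, SD, 9 pairs), and L was denser in 8 of 9 pairs (exact sign-flip permutation p = 0.0117, two-sided). The ratio was largest for pair 3 (1.18, 25.3 against 21.4 per Mb), pair 4 (1.13, 23.8 against 21.0) and pair 1 (1.12, 21.5 against 19.2). In pair 8 the densities were 27.4 and 27.0 per Mb, and in pair 7 the S chromosome was denser (22.0 against 22.5 per Mb). The peak lists of library 1 and library 2 taken alone gave ratios of 1.07 (exact p = 0.0117) and 1.051 (exact p = 0.00781). The test compares chromosome pairs, not embryos, and leaves out regions on unplaced scaffolds. Counting all 5505 scaffolds that held a peak as S, each up to its last peak, turned the ratio of regions per Mb from 1.08 to 0.991, an extreme value because scaffold sequence without peaks is left out.

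**Figure D3:**
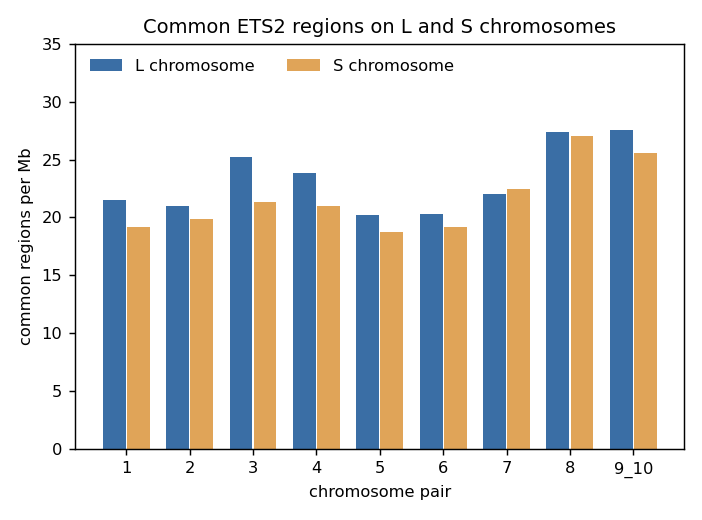
Common ETS2 regions per Mb (y axis, from 0) on the L chromosome and the S chromosome of each of the 9 pairs (x axis). Each bar is 1 count divided by 1 length, without error bars; L is higher in 8 pairs and S in pair 7.

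Along the chromosomes, common regions lay closer together than randomly placed regions, in a comparison added after the data were seen. The placements were uniform up to the last peak of each chromosome and took no account of sequence gaps or gene density. The p-value below therefore speaks only against uniform placement. Among neighbouring regions on a chromosome, 25.6% were less than 5 kb apart, against 11.7% ± 0.131 (SD over 100 random placements within chromosomes, highest 11.9%; permutation p = 0.0099, one-sided, the smallest possible). Of 25092 windows of 100 kb, 6625 (26.4%) held no common region, and 460 held 10 or more, where the random placements gave at most 10 such windows. The densest windows, singled out after their values were seen, were on 2S at 128800001 to 128900000 with 31 regions, on 3L at 136400001 to 136500000 with 27 and on 6S at 33700001 to 33800000 with 27. They were followed by 6L at 39600001 to 39700000 with 26, 8L at 118900001 to 119000000 with 26 and 2L at 148400001 to 148500000 with 25. No window of a random placement held more than 15.

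**Figure D4:**
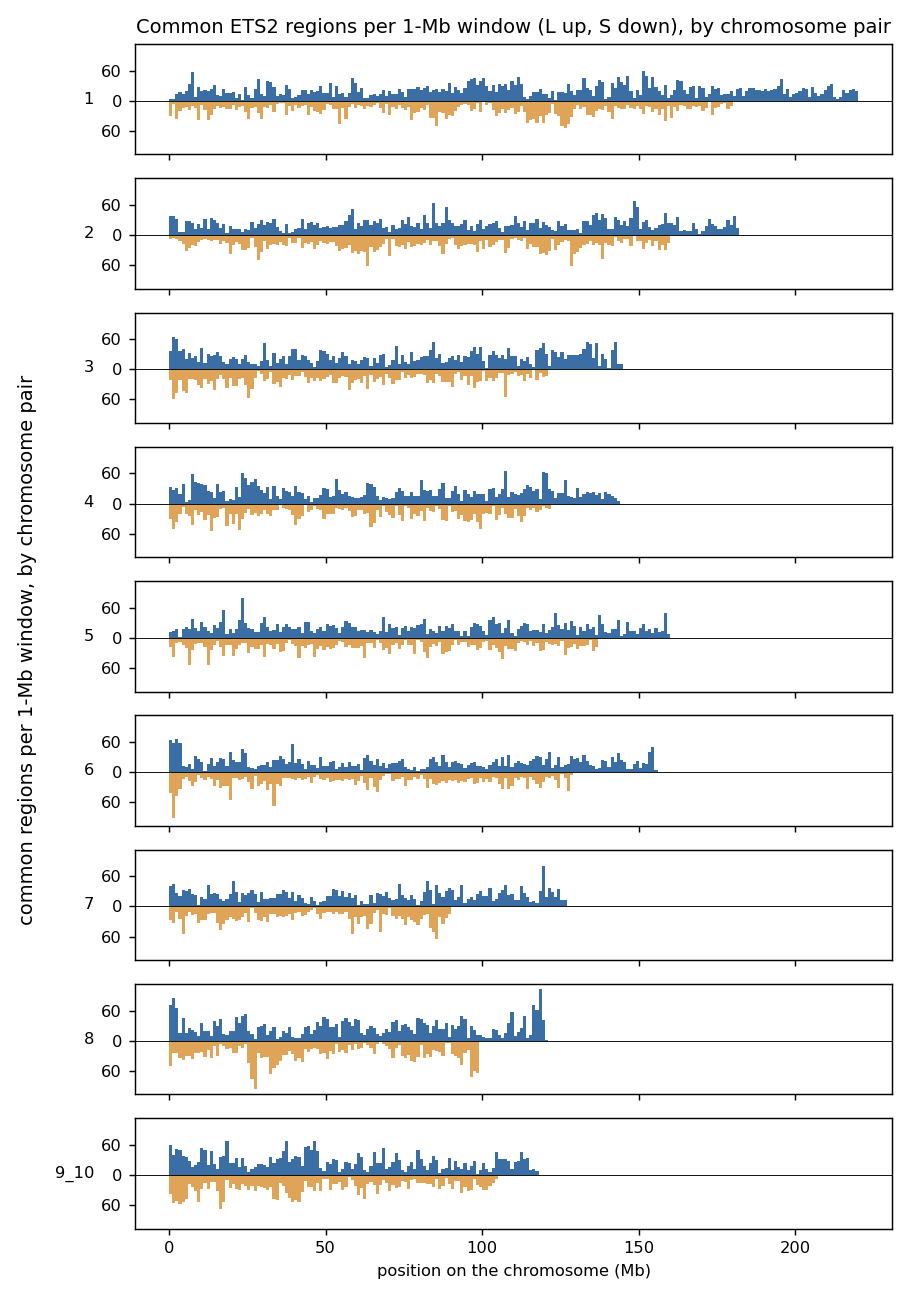
Number of common ETS2 regions per 1-Mb window (y axis; L chromosome upwards, S chromosome downwards) along each of the 9 chromosome pairs (x axis, position in Mb). Counts vary several-fold along every chromosome, and the fullest window, on 8L, holds 103 regions.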

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

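The minimum peak values, the restriction to chromosomes, the changed denominators, the gap sizes and the omission of single chromosome pairs were chosen after the data were seen; the others were fixed before. Library 2 had more peaks than library 1 under every minimum value tried. The ratio was 2.27 with the authors' threshold, 2.37 at a value of at least 5, 2.73 at 10 and 3.86 at 20, and the cause of that rise was not tested; the value is not comparable in size between libraries. The overlap of the libraries exceeded all 100 random placements in every setting tried, with a share of library 1 peaks from 49.5% (reciprocal overlap of at least 50%) to 97.5% (peaks above the median value). The rank correlation of peak values moved from 0.70 to 0.79 with reciprocal overlap, and to 0.51 with adjustment for peak width. The L to S ratio was 1.08 over the common regions and 1.07 among regions above the median rank (exact p = 0.00391). Per 100-kb window with a library 2 peak, and without stretches of 100 or 200 kb that hold none, it was 1.08 (exact p = 0.00781 each). It was 1.051 to 1.073 with 1 library left out, and 1.06 to 1.09 when each chromosome pair was left out (exact p from 0.00781 to 0.0234). The share of close neighbours exceeded all random placements for gaps under 2 kb (14.4% against 5.52%) and under 20 kb (52.0% against 36.8%) as well. No paired analysis was possible because the results come from peak lists and no test across ChIP and input libraries was made; the labels tie each list to 1 ChIP library and 1 input. The alternatives for gene location, motifs and gene lists, and peaks per annotated gene on L and S chromosomes, were not run, since no gene models of the build of the files were used. Unknown depth limits the reading of peaks found in library 2 alone.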

Other observations

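The tests of the highest decile, scaffold shares, large gaps, unplaced scaffolds, profile pairing and chromosome starts were chosen after their results were seen; the other tests in this part were added after the data were seen but before their own results.

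Dense ETS2 windows recurred at matching places of some L and S partner chromosomes. The 50 densest windows of 100 kb held 16 to 31 common regions, and 30 of them were on L and 20 on S chromosomes. The cut at 50 fell within a tie of 13 windows with 16 regions each, only part of which are among the 50. Which of the tied windows entered was arbitrary, and the counts of matches depend on that cut. In 17 of the 50 a dense window of the partner chromosome lay within 2% of the same relative position. Both windows of a match are counted. These windows were on pairs 2, 3, 6, 7 and 9_10, and the dense windows of pairs 1, 4, 5 and 8 had no such counterpart among the 50. The densest, on 2S at 80.6% of its length (31 regions), had a counterpart on 2L at 81.9% (25 regions). The window on 6S at 26.3% (27 regions) matched that on 6L at 25.6% (26 regions), and the window on 9_10L at 57.7% (21 regions) matched that on 9_10S at 59.5% (20 regions). The window on 3L at 94.6% (27 regions) and that on 8L at 99.0% (26 regions) had no such counterpart. Counts in 100 bins per chromosome correlated most between 6L and 6S (rank correlation 0.44), 7L and 7S (0.35) and 9_10L and 9_10S (0.33), and least between 3L and 3S (0.03) and 8L and 8S (−0.01). Common regions were 1.35 times as dense in the first 5% of a chromosome as in its remainder (higher in 13 of 18 chromosomes and, as a mean of L and S, in 7 of 9 pairs; exact sign-flip p = 0.0273 over the pairs, two-sided), and 0.95 times in the last 5% (exact p = 0.652).

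Against an arbitrary pairing of the chromosomes, the mean rank correlation of partners was 0.216, against 0.00623 for other L and S chromosomes (exact p = 1.93e-05 over 362880 pairings), and 0.125 to 0.320 with finer and coarser bins; peaks found in library 2 alone gave 0.208 (exact p = 3.31e-05), so the pattern is not particular to the common regions. Chromosome ends or a few dense bins were not the whole of it, since the correlation was 0.156 without the first and last 10% of each chromosome (exact p = 4.13e-05) and 0.132 without the densest 5% of bins (exact p = 0.00129); removal of as many other bins was not tried, so their own part is unknown. The 17 matched windows exceeded the 5.88 of other pairings (exact p = 0.00866; p from 0.00313 to 0.0317 with 25 or 100 windows or within 5% of the position, and 0.0711 within 1%). Among regions above the median rank 10 matched against 6.88 (exact p = 0.236), which leaves a part for weak peaks near the threshold of library 1 open, although the list of library 2 alone, which does not depend on that threshold, gave 20 against 4 (exact p = 0.000463) and that of library 1 gave 18 against 4.38 (exact p = 0.000479). No biological explanation was tested, and gene density and reads shared between similar L and S sequences, also not tested, stay open.

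For the higher density on L chromosomes, an excess of long stretches without peaks on S chromosomes was argued against. Sequence gaps of 100 kb or longer could not be judged on their own, since they were not separated from other sequence without peaks. Stretches of 100 kb or longer without a library 2 peak, inside which any such gap must lie, made up 16.6% of L and 16.7% of S chromosomes, and without them the ratio was 1.08 (exact p = 0.00781); shorter gaps were not tested. Counting the 5505 scaffolds that held a peak (151.7 Mb up to their last peaks) as S brought the ratio to 0.991, and counting them as L brought it to 1.15, against 1.08 on chromosomes alone; both are extremes, since scaffold sequence without peaks is left out and scaffold density thereby overstated. Sequence gaps and S regions left on scaffolds stay open as explanations, beside a difference between the subgenomes.

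For the larger number of peaks in library 2, the highest decile of library 2 peaks could not decide on a lower sensitivity of library 1. In that decile 99.9% of peaks overlapped a library 1 peak, as a lower sensitivity would give. Weak extra peaks of any origin in library 2 would leave that share as high. In the lowest decile 3.60% overlapped a library 1 peak, against 1.53% of all library 2 peaks on the chromosomes under uniform random placement. Across the 66601 overlapping pairs, library 2 had the higher value in 64810 (97.3%), with median values of 36.3 against 8.79 in library 1. A lower sensitivity of library 1, from fewer reads or weaker enrichment, would give such a shift. These values do not show the origin of the peaks found in library 2 alone. Splitting of regions was argued against, since joining peaks less than 500 bp apart left a ratio of 2.32 (142906 against 61649 regions). Extra peaks on scaffolds were argued against too, since peaks found in library 2 alone were on scaffolds at 0.924 times the share of shared ones. No biological explanation was tested, because both libraries carry the same label.

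Of the 2629 peaks found in library 1 alone, 845 (32.1%, 95% interval 30.4 to 34.0%) lay on scaffolds, against 9.27% of shared library 1 peaks. Of these 845, 678 were on scaffolds whose last peak ended within 10 kb, and 661 were on scaffolds without any library 2 peak. The strongest peaks found in library 1 alone were on Scaffold215316 (1 to 133, value 104) and Scaffold172694 (1 to 148, value 98.0). In library 2 the strongest were on Scaffold90945 (1 to 248, value 164) and Scaffold92725 (1 to 243, value 151), followed by a peak on 2L at 148821689 to 148822201 with a value of 94.6. Each of the named scaffold peaks began at the first base of its scaffold, and no list held a peak beyond its end. The full lengths of these scaffolds are unknown, since lengths were taken from the last peak.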
